A study of Caenorhabditis elegans with 2 samples.

How the data were processed

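Chromatin immunoprecipitation with an anti-GFP antibody followed by sequencing was used to map sites occupied by DSC-1 in whole Caenorhabditis elegans larvae of strain OP522, whose transgene carries DSC-1 with a carboxy-terminal GFP-FLAG tag, per the labels. The animals were hermaphrodites at the first larval stage (L1), collected 6 hours after synchronization as starved L1 after bleaching, per the labels. The labels give 1 group with 2 biological replicates, so no comparison between conditions was possible. A control experiment is named in the labels and was not analysed here.

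The authors deposited 8 peak lists. For each of the genome builds ce10 and ce11 there is a list for each replicate and a list for the pooled replicates. A further list for each build holds the pooled peaks that passed the authors' irreproducible discovery rate (IDR) threshold. The IDR measures how reproducible the ranks of peaks are between replicates. The authors name the replicate and pooled lists as peaks together with background that served as input to the IDR step. The read aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each deposited peak has a signal value from the authors' peak caller, a q-value written as −log10, and the offset of the summit from the start of the peak. The scale of the signal value is not stated, so the deposited signal was used only to rank or compare peaks within a list, or to correlate lists by rank and on a log scale. The −log10 q-value reached a ceiling of 4.07 for 5914 of the IDR peaks and was not used for ranking. The number of reads per library is not contained in the peak lists, so the depth of each replicate is unknown.

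Positions are given on ce11, 1-based. Gene models were those of Ensembl release 115 for WBcel235, the assembly that ce11 names, and sequence came from the same assembly. The ce10 lists entered only counts and the comparison of replicates, and no coordinates were converted. The main set was the IDR list on ce11 with 6283 peaks. In replicate comparisons each replicate was represented by as many of its strongest peaks as there are IDR peaks, and an overlap of at least 1 bp counted as shared. Chance overlap was the mean over 20 circular shifts of the IDR peaks along each chromosome. The IDR list was built from both replicates, so this overlap is not an independent measure of reproducibility.

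A promoter window ran from 1000 bp upstream to 200 bp downstream of the start of each of 19973 protein-coding genes, with the outermost annotated start of the gene. Many nematode transcripts are trans-spliced, so annotated starts can lie downstream of the site where transcription begins. The share of summits in promoter windows was compared with 1000 random placements of the same number of summits on the same chromosomes by a one-sided permutation test, for which the smallest p is 0.000999. Positions in gene models and the biotype of the nearest gene start within 1000 bp were compared with random placements in two-sided permutation tests, whose smallest p is 0.0020. For each of 19 gene lists, members with a summit in the promoter window were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 19 lists. Genes and peaks are not replicates, and these tests describe this peak list. In the respiratory chain list 2 symbols, cco-1 and cco-2, had no match in the annotation.

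Words were searched on both strands in the 101 bp around each summit and in windows of the same width centred 300 bp to each side, with an exact McNemar test against each side and Benjamini-Hochberg adjustment over the 24 words and both sides. A rule dropping summits within 100 bp of a stronger summit removed no peak. Intervals of shares are exact Clopper-Pearson 95% intervals and cover counting error only.

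The genes named are dsc-1, exp-1 and unc-119; the genes with a promoter summit among the 25 strongest IDR peaks, or the nearest gene start where there is none; and for each list up to 4 members with the strongest promoter peaks, each with any divergent neighbour that shares the summit. Some genes that this rule names are not reported here. The lists, words, tests, naming rule and main alternatives were set before the data were examined. Alternatives were the stronger 50% of peaks, each replicate alone, merged regions, the ce10 lists, other overlap rules, other promoter windows and gene starts, other null placements, lists matched on upstream intergenic length, and other word windows and backgrounds. Restriction to autosomes or to X, and each replicate alone for biotypes and for the loci of the transgene, were added after the data were examined.

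The tests were tested on simulated data. With 6283 simulated peaks and 19973 genes, all 20 lists of 40 genes in which peaks were planted at 50% of members were recovered, and 1 of 180 lists without planted peaks was called. Planting at 50% of members is a large effect, so this recovery does not show that smaller differences would be found. Of 40 sets of randomly placed peaks, 2 were called near gene starts. Of 40 random summit sets, each smaller than the IDR list, 0 were called for TAATTA on both sides. Random positions lack the higher GC content of the IDR summits, so this does not show how the word test behaves there. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.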

Results

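DSC-1 is a paired-like homeodomain protein of C. elegans with a known role in the defecation motor program, where it is needed in enteric muscles for expression of exp-1, a GABA-gated cation channel. Chromatin immunoprecipitation of a GFP-tagged transgene was used to map genomic sites of DSC-1 in whole L1 larvae, in 2 biological replicates of 1 group. The control was not analysed here, and which peaks reflect DSC-1 itself was not tested. The deposited lists held 26482 peaks for replicate 1, 30000 for replicate 2 and 30000 for the pooled replicates on ce11, of which 6283 pooled peaks passed the authors' IDR threshold. These IDR peaks had a median width of 396 bp and together covered 2010 kb. They were also the 6283 pooled peaks with the highest signal. Membership therefore does not show that a single peak was found in both replicates, and 6232 of them overlapped a peak in both replicate lists. On ce10 the threshold left 6192 peaks.

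Both replicates contained most of the IDR peaks among their strongest peaks. The 6283 strongest peaks of replicate 1 overlapped 90.4% of IDR peaks (95% interval 89.6 to 91.1), and those of replicate 2 overlapped 92.2% (91.5 to 92.9), where shifted peaks gave 4.19% in each. Peak signal ranked similarly in both replicates, with a Spearman correlation of 0.852 and a Pearson correlation of log signal of 0.875 across 6232 IDR peaks found in both lists. This correlation is across peaks, which are not independent replicates and were selected on these same libraries. Of the 500 strongest peaks of replicate 1, 82.4% overlapped the 500 strongest of replicate 2. Requiring a reciprocal overlap of 50% lowered the share of IDR peaks shared with replicate 1 to 73.8%.

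The IDR peaks lay near gene starts more often than random positions. Of the 6283 summits, 2429 fell in the promoter window of a protein-coding gene, a share of 38.7% (37.5 to 39.9), against a mean of 21.1% for random placements (p = 0.000999, permutation test, the smallest the placements can give). A promoter summit was present at 2944 of 19973 protein-coding genes, or 14.7%, and 666 summits lay in the windows of more than a single gene. Summits were found in coding exons at 5.25%, against 24.3% for random positions, and in 3′ UTRs at 1.53% against 3.36%. They were found in 5′ UTRs at 2.79% against 1.42%, in introns at 27% against 33.5%, and outside protein-coding genes at 63.5% against 37.5% (p = 0.0020 for each of these 5 locations, permutation test, the smallest possible). Each replicate alone gave a promoter share close to that of the IDR list, 38.9% for replicate 1 and 38.0% for replicate 2.

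Among the 25 strongest peaks, those with a summit in a promoter window included 4 genes of cytosolic ribosomal proteins. The second strongest peak (chromosome III, 3867338 to 3867784) had its summit 281 bp upstream of rpl-3. Peaks at rank 9, 16 and 23 lay 305 bp upstream of rpl-20, which shares the summit with Y17G9B.5, 446 bp upstream of rpl-35, and 349 bp upstream of rpl-15, which shares it with K11H12.8. Further promoter peaks in this set were at egg-5 (rank 8, 578 bp upstream), a gene acting at the oocyte-to-embryo transition, and at cdc-48.1 (rank 10, 161 bp upstream), which encodes a AAA ATPase that unfolds ubiquitinated proteins. The remaining ones were at nspc-17 (rank 12), F10C5.3 (rank 14), tasp-1 with its neighbour K01G5.10 (rank 15), H41C03.3 (rank 20) and cox-5A (rank 25), a subunit of cytochrome c oxidase. With replicate 1 alone, egg-5 was at rank 5, cdc-48.1 at rank 4, rpl-3 at rank 1, rpl-35 at rank 9, H41C03.3 at rank 12 and nspc-17 at rank 30, and with replicate 2 alone nspc-17 was at rank 7.

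The other strongest peaks had no protein-coding gene start within the window, and 13 of them were on X. Starts of non-coding genes were not considered for these peaks. The strongest peak of the whole list (X, 16681842 to 16682391) had its summit outside protein-coding genes, 2567 bp downstream of the start of F22H10.2. The nearest protein-coding gene starts to the X peaks at ranks 3 to 7 were those of W02H3.3, K02D3.1, F20B6.9, ZK899.6 and F55G7.5. The distances were 3982, 6057, 1790, 2510 and 1393 bp. The peak at rank 11 (X, 8036043 to 8036943) lay 4872 bp upstream of xol-1, a gene that acts in sex determination and X dosage compensation. Those at ranks 13, 17, 19, 21, 22 and 24 were nearest to cest-16, Y41G9A.17, C41A3.2, T27A8.7, gtr-1 and F19H6.5. On autosomes, the peak at rank 18 was 4774 bp upstream of cmd-1, the calmodulin gene.

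X carried more peaks than its length or gene content. It held 1463 IDR summits, or 23.3% of them (22.2 to 24.4), with 17.7% of the genome length and 13.7% of protein-coding gene starts. Peak density was 82.6 per Mb on X and between 51.9 per Mb on V and 69.1 per Mb on III for the autosomes. Before the IDR threshold, X held 6413 of 30000 peaks in the pooled list, 5688 of 26482 in replicate 1 and 6304 of 30000 in replicate 2. These lists include background and also exceed the share of length, so an excess on X is not particular to the IDR peaks. X held 18 of the 50 strongest peaks, 15 of them outside promoter windows. Over all IDR peaks, 30.1% of X summits (27.8 to 32.6) and 41.2% of autosomal summits (39.9 to 42.6) were in promoter windows. Among the 500 strongest peaks, the corresponding shares were 24.1% of 116 on X (16.7 to 33) and 57% of 384 on autosomes (51.9 to 62). Random placements gave means of 17.4% on X (p = 0.0450, permutation test) and 22.1% on autosomes (p = 0.000999, permutation test). Neighbouring summits are not independent, and the intervals cover counting error only.

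**Figure D1:**
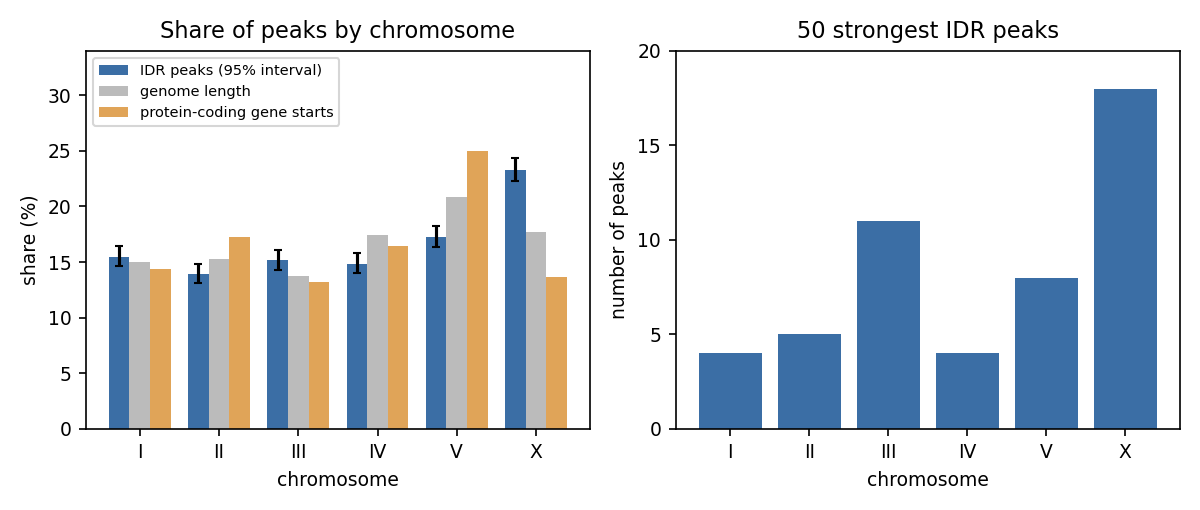
Left, share (%) of the 6283 IDR peaks on each chromosome with exact 95% binomial intervals, beside the share of genome length and of protein-coding gene starts; right, number of the 50 strongest IDR peaks per chromosome. X holds 23.3% of peaks with 17.7% of the length, and 18 of the 50 strongest peaks.

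Gene lists differed in how often their members carried a promoter summit. Of 19 lists, 5 carried summits more often than other protein-coding genes and 4 less often (Fisher's exact test, adjusted p under 0.05). Cytosolic ribosomal protein genes had the highest share in promoter windows, with 64 of 82 genes (odds ratio 21, exact adjusted p = 1.18e-36), led by rpl-3, rpl-20, rpl-35 and rpl-15. Respiratory chain genes followed with 27 of 42 (odds ratio 10.5, exact adjusted p = 2.05e-12). Their strongest promoter peaks were at cox-5A, at atp-1 (rank 262, shared with mcrs-1), which encodes a subunit of ATP synthase, at the Rieske protein gene isp-1 (rank 438), and at mev-1 (rank 498, shared with jmjd-4), which encodes a subunit of succinate dehydrogenase. The order of the lists depended on the assignment of summits: with each summit given only to its nearest gene start, ribosomal protein genes had 41 of 82 (odds ratio 4.15, exact adjusted p = 2.73e-09; range over the alternatives 1.57e-38 to 0.000950) and respiratory chain genes 20 of 42 (odds ratio 3.76, exact adjusted p = 0.000140; range 1.97e-12 to 0.000950). Body-wall muscle genes then had 32 of 42 (odds ratio 13.3) and pan-neuronal genes 26 of 36 (odds ratio 10.8). The ranks here and in the following are by the authors' signal within the IDR list.

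Genes of contractile and neuronal proteins were also among the lists with more summits. Body-wall muscle genes had 22 of 42 (odds ratio 6.40, exact adjusted p = 5.73e-08), with the troponin genes mup-2 (rank 757), pat-10 (rank 1127, shared with C46H11.6) and unc-27 (rank 1159) and the actin gene act-4 (rank 817, in its 5′ UTR). Pan-neuronal genes had 13 of 36 (odds ratio 3.28, exact adjusted p = 0.00338), with rund-1 (rank 1049), the liprin gene syd-2 (rank 1089), the synaptotagmin gene snt-1 (rank 1296) and ric-19 (rank 2384, shared with pmlr-1). Heat shock protein genes had 10 of 22 (odds ratio 4.83, exact adjusted p = 0.00177), with the mitochondrial chaperonin gene hsp-60 (rank 26, shared with Y22D7AL.10), the HSP70 genes hsp-1 (rank 58) and hsp-3 (rank 773), and hsp-110 (rank 131, shared with the proteasome gene rpn-3). The pan-neuronal call was lost with the stronger 50% of peaks (adjusted p = 0.437) and the heat shock call when each summit was given only to its nearest gene start (adjusted p = 0.236), with adjusted p of the 10 alternatives from 6.98e-11 to 0.437 for the former and from 0.00140 to 0.236 for the latter in exact and permutation tests. With replicate 1 alone, hsp-1 was at rank 122, hsp-60 at rank 17 and ric-19 at rank 1477, and with replicate 2 alone ric-19 was at rank 3647. Actin and small heat shock genes belong to families of similar sequence, and whether reads were shared among copies is not given in the sources used here.

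Chemoreceptor genes had the lowest share among the lists past the test, 20 of 1217 (odds ratio 0.0905, exact adjusted p = 1.11e-57). The strongest of these peaks, at sri-5 (rank 318), was shared with the neighbour rsr-1, and those at srd-3 (rank 711) and srsx-18 (rank 1572) were not shared. Collagen genes had 7 of 156 (odds ratio 0.270, exact adjusted p = 0.000227). Of the 4 strongest collagen peaks, those at col-148 (rank 241), col-71 (rank 389) and col-38 (rank 1103) were shared with C12D8.21, Y49F6B.2 and the ribosomal protein gene rpl-5, and the summit at col-63 (rank 1587) lay in a 3′ UTR. With replicate 1 alone, col-71 was at rank 253 and col-63 at rank 967. Intestinal genes had 1 of 47 (odds ratio 0.125, exact adjusted p = 0.0269), the single gene being erm-1 (rank 3041), and genes of hypodermis and cuticle had 1 of 43 (odds ratio 0.137, adjusted p = 0.0340), the single gene being dpy-8 (rank 4387, summit in a coding exon). The intestinal call was lost in 5 of 10 alternatives, with exact or permutation adjusted p from 0.0170 to 0.389, the hypodermal call in 3 of 10, with adjusted p from 0.00442 to 0.165, and the collagen call in 1 of 10, with adjusted p from 0.000228 to 0.0971.

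**Figure D2:**
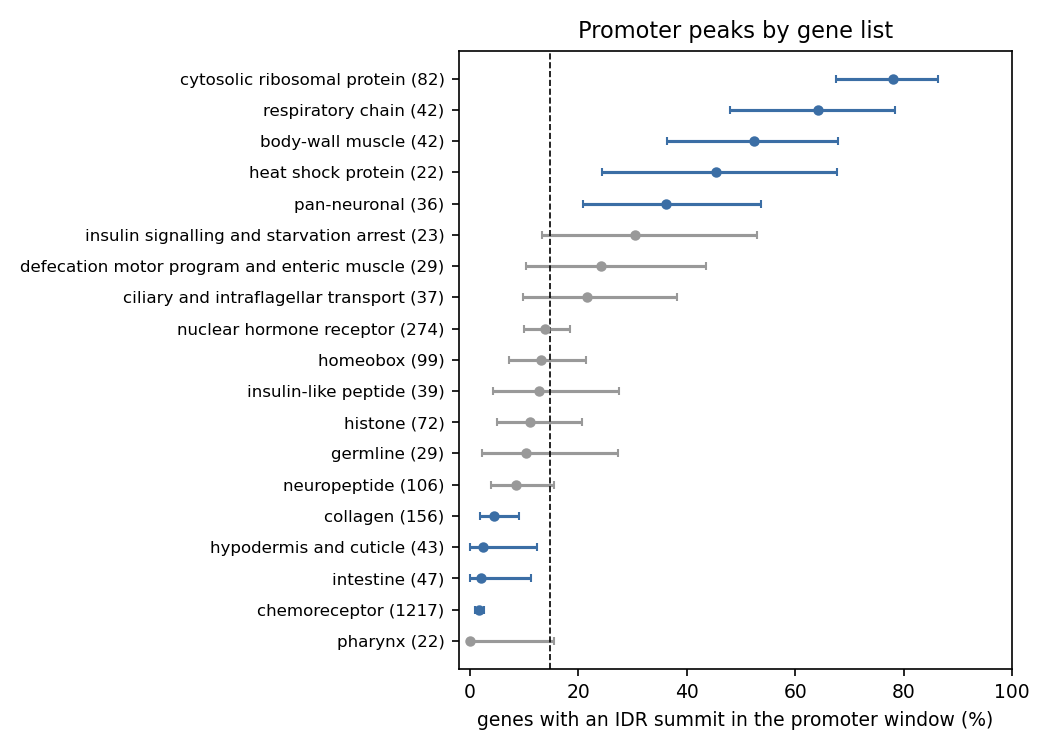
Share (%) of the genes of each of 19 lists with an IDR summit in the promoter window, with exact 95% binomial intervals and the number of genes in brackets; blue, adjusted p under 0.05, grey, not past this threshold; the dashed line is the 14.7% of all protein-coding genes. Cytosolic ribosomal protein genes reach 78.0% and chemoreceptor genes 1.64%.

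The other 10 lists did not pass the test. Among transcription factors, 13 of 99 homeobox genes (exact adjusted p = 0.836) and 38 of 274 nuclear hormone receptor genes (adjusted p = 0.836) had a promoter summit. The strongest homeobox peaks were at ceh-23 (rank 237), ceh-38 (rank 500, shared with malt-1), the Hox gene mab-5 (rank 1325) and the PBX-type gene ceh-20 (rank 1351), and the strongest receptor peaks were at nhr-196 (rank 143), nhr-68 (rank 224, shared with H12C20.7), nhr-47 (rank 231, shared with the chaperone gene dnj-19) and nhr-158 (rank 377). With replicate 1 alone, nhr-68 was at rank 408. With each summit given to its nearest gene start, receptor genes had more summits than other genes (odds ratio 1.39, exact adjusted p = 0.0402; range over the alternatives 0.0402 to 1). Of secreted peptides, 9 of 106 neuropeptide genes (exact adjusted p = 0.117; nlp-47, nlp-3, nlp-1 and ntc-1) and 5 of 39 insulin-like genes (adjusted p = 1) had summits. The insulin-like genes ins-39 (rank 50) and ins-14 (rank 272, shared with F41G3.5) had the strongest peaks of these, followed by ins-18 (rank 1982) and ins-15 (rank 5514). With replicate 2 alone, 3 of 39 insulin-like genes had summits (odds ratio 0.498, against 0.850 with all IDR peaks), and with the nearest gene start the odds ratios were 1.42 for insulin-like and 1.41 for neuropeptide genes, neither past the threshold. Insulin signalling and starvation arrest genes had 7 of 23 (exact adjusted p = 0.117), including the kinase genes akt-1 (rank 1912) and akt-2 (rank 2992) and daf-1 (rank 3853). This list passed in 2 of 10 alternatives, with exact or permutation adjusted p from 0.00136 to 0.648.

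For ciliary and intraflagellar transport genes the count was 8 of 37 (exact adjusted p = 0.330), including ift-81 (rank 1979), the RFX factor gene daf-19 (rank 2020), dyf-6 (rank 2336) and tub-1 (rank 3626, shared with tmem-138). With replicate 2 alone it was 5 of 37, and the odds ratio moved from 1.60 to 0.935. Germline genes had 3 of 29 (adjusted p = 0.836), namely mes-2 (rank 748), spo-11 (rank 3685, shared with swsn-4) and mes-6 (rank 5256, shared with tag-77), and pharyngeal genes had 0 of 22 (exact 95% interval up to 15.4%; adjusted p = 0.117). Histone genes had 8 of 72 (exact adjusted p = 0.639), with the strongest peaks at his-37 (rank 77), at the summit shared by his-35, his-41 and C50F4.6 (rank 1058), and at his-72 (rank 2564, shared with rpt-6). Most histone genes are present in near-identical copies, so peaks there are uncertain. With replicate 1 alone, 5 of 72 histone genes had a summit (odds ratio 0.423, against 0.722 with all IDR peaks), and mes-2 was at rank 496. The pharyngeal, histone and neuropeptide lists each passed in 1 of 10 alternatives, with lowest exact or permutation adjusted p of 0.0280, 0.0382 and 0.0471.

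Genes of the defecation motor program and enteric muscle had a promoter summit at 7 of 29 members (odds ratio 1.84, exact adjusted p = 0.268), which did not pass the test. The list passed in 1 of 10 alternatives, in which each summit was given to its nearest gene start (exact adjusted p = 0.0389; range 0.0389 to 0.703). The strongest peak was 59 bp upstream of egl-30 (rank 92, shared with C53H9.4), a Gq alpha subunit gene. Next were aex-2 (rank 1167, 542 bp upstream), which encodes a G-protein-coupled receptor, the inositol trisphosphate receptor gene itr-1 (rank 2574) and the SNAP25 homologue gene aex-4 (rank 2867, 209 bp upstream). At exp-1 (chromosome II, 6157144 to 6161094, minus strand) there was a summit 703 bp upstream of the start at rank 3865, with rank 4318 in replicate 1 and 3832 in replicate 2. A stronger peak lay outside the window, 1435 bp upstream (II, 6162383 to 6162664), at rank 1091, with rank 1085 in replicate 1 and 1079 in replicate 2. Both summits lie outside protein-coding genes.

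The loci represented in the transgenic strain were examined separately, since a transgene can add copies of them. No IDR peak lay within 20 kb of dsc-1 itself (X, 15031180 to 15034832, minus strand), and neither full replicate list had a summit there, where the genome-wide average would give 11.5 and 13.1 summits in a stretch of that length. The pooled list had 1, at rank 23841. The stretch without a summit was 61.2 kb long in replicate 1 and 70.7 kb long in replicate 2, and 3 of 5687 gaps between X summits were longer in replicate 1 and 5 of 6303 in replicate 2. At unc-119 (III, 10902641 to 10908935), the gene mutated in this strain, 3 IDR summits lay inside the gene, 860, 2723 and 3870 bp downstream of its start, at ranks 1147, 3338 and 5707. None was in its promoter window. Another summit at rank 5373 was 6624 bp upstream of the start. The average for a stretch of the gene with 20 kb on each side is 2.9 IDR peaks, and 4 were found. Cut to as many of their strongest peaks as there are IDR peaks, replicate 1 gave 2 and replicate 2 gave 4. The full lists held 17 summits there in replicate 1, 21 in replicate 2 and 24 in the pooled list. The averages were 12.2, 13.9 and 13.9. Around exp-1 the same lists held 17, 21 and 23, against averages of 11.6, 13.1 and 13.1. Why these counts exceed the averages was not tested.

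**Figure D3:**
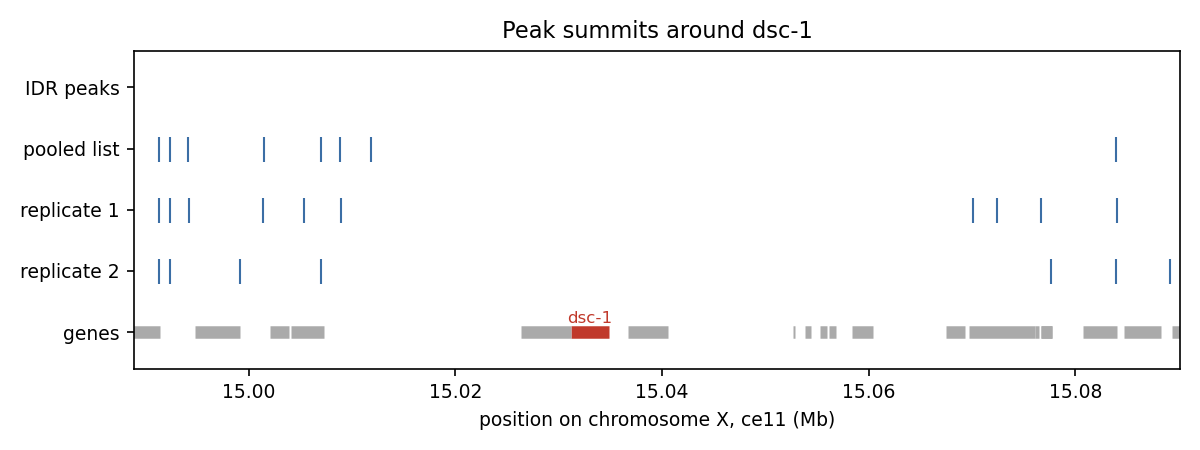
Summits (vertical marks) of the IDR list, the pooled list and both replicate lists around dsc-1 on chromosome X, with protein-coding genes below and dsc-1 in red; the x axis is the ce11 position in Mb. No summit of either replicate lies in the 61.2 kb between 15008940 and 15070120.

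Several classes of non-coding genes had more summits near their starts than random placements gave. Summits whose nearest gene start within 1000 bp was that of a tRNA gene numbered 207, against a random mean of 36, a ratio of 5.74. For snoRNA genes there were 114 against 27.2, for snRNA genes 23 against 7.06, and for genes annotated as ncRNA 927 against 548. Protein-coding genes had 2332 against 1933. The adjusted p was 0.00314 for each of these classes (permutation test), from the smallest unadjusted p the placements can give. Fewer summits than random were nearest to pseudogenes, with 52 against 189, and to piRNA genes, with 177 against 293 (adjusted p = 0.00314 for both, permutation test). For miRNA genes 29 summits were counted against 19 (adjusted p = 0.0604), which passed the threshold within 500 bp with a ratio of 1.93 (adjusted p = 0.00824) and with replicate 1 alone (adjusted p = 0.0269), with a range over the alternatives of 0.00824 to 0.386 in permutation tests. For lincRNA genes 26 were counted against 18 (adjusted p = 0.10), and among the alternatives it passed with replicate 1 alone (permutation adjusted p = 0.0220; range 0.0220 to 0.176). Antisense RNA genes (5 against 8.07) and rRNA genes (0 against 0.907) did not pass. Transfer RNA and snRNA genes are multicopy, and how the authors placed reads from copies is not given in the sources used here.

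Sequence at the summits was examined for homeodomain sites and for other words set beforehand. TAATTA, the core of many homeodomain sites, occurred within 50 bp of 285 of 6283 summits, or 4.54% (4.03 to 5.08), against 5.57% and 5.43% of the flanking windows, a ratio of 0.825 (exact McNemar test, adjusted p = 0.0190 and 0.0460). Alternatives were judged by the higher unadjusted p of both sides. The difference was then not past 0.05 with the stronger 50% of peaks (ratio 0.868), replicate 2 alone (0.845) or flanks at 1000 bp (0.870). The ratio was 0.655 at 2429 promoter summits (exact McNemar test, p = 0.000627 and 0.00200), 0.948 at the 3854 other summits (p = 0.567 and 0.675), 0.935 on X (p = 0.168 and 0.539) and 0.793 on autosomes (p = 0.0302 and 0.00313), unadjusted, and the differences between these sets were not tested. The palindromic dimer TAATNNNATTA occurred at 39 summits, or 0.621% (0.442 to 0.848), with a ratio of 1.22 to the flanks (adjusted p = 0.663 and 0.424, exact McNemar test), and of the other 10 spacings, none had a higher share at summits past the threshold. Its ratio was 0.552 at promoter summits (8 of 2429; p = 0.210 and 0.286, exact McNemar test) and 1.77 at the others (31 of 3854; p = 0.111 and 0.0400), unadjusted, and the difference was not tested. Other words were more frequent at summits. GAGAGA was found at 20.8% of summits (19.8 to 21.8) against 6.68% and 5.94% of flanks. CTGCGTCT was found at 6.18% (5.59 to 6.80) against 0.573% and 0.493%, a ratio of 11.6, and its share was 7.32% in the strongest quintile of peaks (5.94 to 8.90) and 4.54% in the weakest (3.46 to 5.84). GCGCGC had a ratio of 5.85 and the E-box CACGTG a ratio of 2.65, while TGATAA, a GATA factor site, had a ratio of 0.660. In exact McNemar tests, the higher adjusted p of both sides was 1.17e-117 for GAGAGA, 6.46e-76 for CTGCGTCT, 1.31e-36 for GCGCGC, 1.03e-16 for CACGTG and 5.11e-11 for TGATAA. Mean GC content was 42.6% at summits, 34.9% and 34.6% in the flanks and 35.4% in the genome, and of the 7 other AT-only palindromic hexamers, all had ratios below 1, from 0.346 to 0.891.

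**Figure D4:**
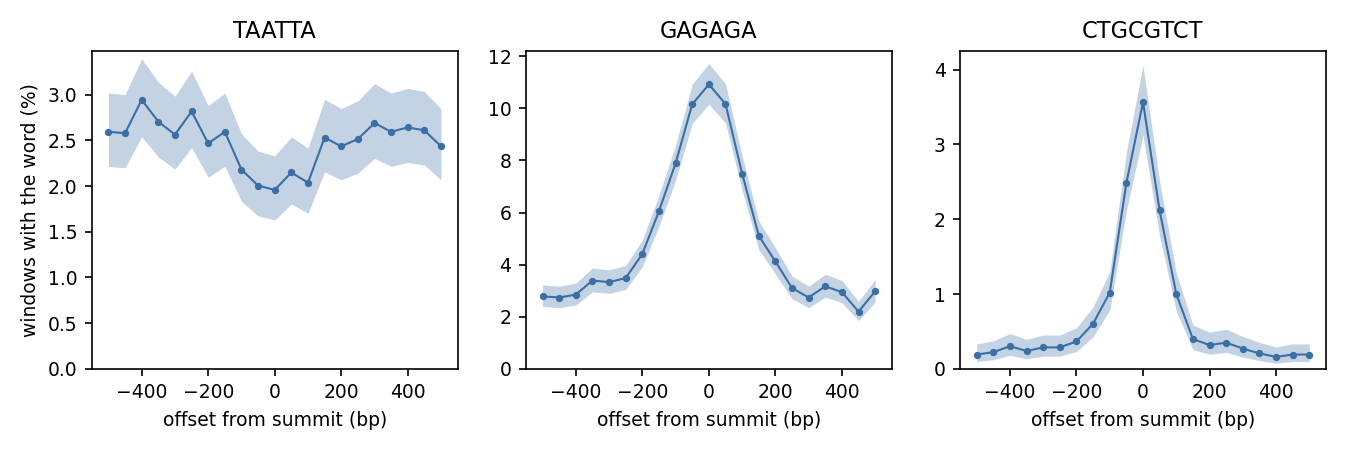
Share (%) of windows of 51 bp with TAATTA, GAGAGA or CTGCGTCT, by offset in bp from the IDR summit, with shaded exact 95% binomial intervals. GAGAGA and CTGCGTCT peak at the summit, and TAATTA does not.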

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

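The alternatives were set before the data were examined, except the restrictions to autosomes and to X and the use of each replicate alone for biotypes and transgene loci, which were chosen after seeing the data. No paired analysis was possible because there is only 1 group. With 2 replicates and no read counts in the peak lists, the replicates were compared by overlap and signal only, and a peak below the authors' threshold in a replicate cannot be told from a shallower library.

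The promoter share of IDR peaks stayed above random placement in every alternative run for it, with shares from 29.5% to 52.2% (p = 0.000999 in each, the smallest the permutations can give), and the X share stayed within 22.9% to 23.3%. The number of lists with more summits ranged from 4 to 7 around the main 5, and that of lists with fewer fell from 4 to 1 with the stronger 50% of peaks and to 2 with the window from 500 bp upstream to 100 bp downstream, where fewer genes have a summit. The stronger 50% of peaks number 3141 by construction, and the other alternatives gave from 4820 to 6250 peaks. Giving each summit to its nearest gene start within 5000 bp reversed the direction for nuclear hormone receptor genes (odds ratio 1.39, exact adjusted p = 0.0402; range over the 10 alternatives 0.0402 to 1), and the cause was not tested.

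The share of IDR peaks overlapped by replicate 1 moved to 86.7% with summits within 100 bp, 73.8% with a reciprocal overlap of 50%, 99.2% with 2 times as many peaks and 99.7% with the whole list, and that for replicate 2 to 90.1%, 82.5%, 99.4% and 99.5%, as looser and stricter rules must. The rank correlation of signal was 0.844 with summits within 100 bp and 0.798 with a reciprocal overlap of 50%. The TAATTA ratio stayed below 1 in the 9 alternatives. By the higher unadjusted p of both sides, it was no longer past the threshold with the stronger 50% of peaks (0.868, exact McNemar p = 0.360, with fewer summits tested) or with flanks at 1000 bp (0.870, p = 0.105, cause not tested); each replicate alone gave 0.834 and 0.845, the latter from replicate 2 with p = 0.0529, and p over the 9 alternatives ran from 6.45e-05 to 0.360. Near unc-119, replicates 1 and 2 gave 2 and 4 summits when cut to as many of their strongest peaks as there are IDR peaks. Of 75 named genes with a promoter summit, 73 kept it among the strongest peaks of both replicates, the exceptions being tub-1 and ins-15. Among named genes, lists and biotypes, 335 of the values under alternatives kept their call or stayed close in rank. Of the others, 11 lost a call, 9 gained 1 and 15 moved in rank. A kept call is not a kept direction where neither setting passed the threshold. For ciliary genes the odds ratio went from 1.60 to 0.935 with replicate 2 alone.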

Other observations

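The tests on GC content, on the control library and on the word GGATTA were chosen only after the result was seen; the other tests in this part were written down before their results.

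Beyond the lists set beforehand, 123 families of 10 or more genes sharing a symbol prefix and no list member were compared with all other protein-coding genes, and 16 carried promoter summits more often and 10 less often (Fisher's exact test, adjusted over 175 families). Nucleoporin genes had 15 of 26 (exact adjusted p = 9.69e-06; npp-3, npp-8 and npp-13 led), vacuolar sorting genes 15 of 31 (adjusted p = 0.000148; vps-32.1, vps-22), and mitochondrial large ribosomal subunit genes 16 of 41 (adjusted p = 0.00127; mrpl-28, mrpl-12). Translation initiation factor genes had 11 of 25 (exact adjusted p = 0.00334; eif-3.B at rank 82), DNAJ chaperone genes 12 of 29 (adjusted p = 0.00349; dnj-13 at rank 54), TATA-binding protein associated factor genes 8 of 17 (adjusted p = 0.00881) and proteasome regulatory genes 6 of 13 (adjusted p = 0.0294; rpn-3, which shares its summit with hsp-110). Among those with fewer were C-type lectin genes with 7 of 240 (exact adjusted p = 6.93e-08), F-box genes of the fbxa type with 7 of 170 (adjusted p = 0.000158), cytochrome P450 genes with 2 of 74 (adjusted p = 0.00881) and transthyretin-related genes with 1 of 58 (adjusted p = 0.0122). These genes were named after their values were seen, and several of the families lie in tandem arrays, so their members are not independent. Families were compared with the promoter window only, not with each summit given to its nearest gene start. That assignment lowered the odds ratio of ribosomal protein genes from 21 to 4.15.

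All words of 6 bases, each taken with its reverse complement, were then compared between summits and flanks, and 747 were higher and 420 lower at summits past an adjusted p of 0.05. Apart from the words set beforehand, 23 words that did not overlap GAGAGA or CTGCGTCT by 5 bases had a ratio above the 3.30 of GAGAGA, led by ACGCGC and CGCGCG (ratios 5.55 and 5.54), most of them rich in CG. Among the 48 words with TAAT or ATTA, 8 were higher at summits and 22 lower past an adjusted p of 0.05, and GGATTA (reverse complement TAATCC) had the highest ratio. It was present at 666 summits, 10.6% (9.85 to 11.4), against 3.92% and 3.47% of flanks, a ratio of 2.87 (exact McNemar test, adjusted p = 1.58e-46). Of the 89 other words with the same bases, 0% had a ratio as high, and their median was 0.922. The next highest was CTAATC with 2.81, which overlaps the reverse complement of GGATTAG and so is not independent of it. GGATTA was picked for its high ratio in this same scan, so its place above these words is not an independent test. The median shows only that words of these bases, as a set, were not more frequent at summits. The ratio of GGATTA was 3.34 in the strongest quintile and 2.42 in the weakest. It was 3.18 at summits with neither GAGAGA nor CTGCGTCT, and 4.04 on X and 2.59 on autosomes. With a further base, GGATTAG had a ratio of 5.90. As a hypothesis, a homeodomain protein that reads TAATCC rather than TAATTA may occupy part of these sites. The comparison with words of the same bases bears on base composition only, and which protein binds was not tested. Peaks of another factor at the same stage, which would bear on this hypothesis, were not analysed here.

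Many of the 50 strongest peaks lay on X outside promoter windows, 15 in all. The central 51 bases of 0% of these summits occurred more than once in the genome (0 of 15, which allows up to 21.8%), which argues against sequence present in several copies as the source of most of them. TCGCGCAGGG, a word of X recruitment sites of the dosage compensation complex, was within 100 bp of 7 of the 15 summits (46.7%, 21.3 to 73.4), of 2 of the 3 X summits inside windows, of 3 of 1445 X summits of lower rank and of 0 of 4820 autosomal summits, and 14 of its 19 copies on X but 0 of 6 on autosomes had an IDR summit within 100 bp. Signal at such recruitment sites is a candidate explanation for strong X peaks inside or outside windows. The counts show that the word lies at part of the strong X peaks, and what produces signal there was not tested. By the rule set beforehand the explanation is left open, as the share in the other 35 of the 50 strongest (5.71%) was above the bound of 5%. The 2 of these 35 summits with the word were the X summits inside windows, so passing the bound does not count against the explanation. Fisher's exact test gave p = 0.00162, which mostly sets X against the 32 autosomal peaks among the 35. TAATTA sites for the DSC-1 homeodomain were at 0% of the 15 (0 of 15, up to 21.8%), too few summits to exclude the 20% set as needed. The other 35 of the 50 strongest summits also had TAATTA at 0 of 35 (up to 10%). No biological explanation was tested against another condition, as there is a single group.

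TAATTA was less frequent at summits than in their flanks over all IDR peaks, with a ratio of 0.655 at promoter summits and 0.948, not past the threshold, at the others. At the 4810 summits with neither GAGAGA nor CTGCGTCT the ratio was 0.932 (bootstrap 95% interval 0.801 to 1.08), below the 1.2 set as needed. Peaks with these words therefore do not hide an excess of TAATTA over flanks of that size. An excess relative to base composition was not tested, because the other AT-only hexamers were not examined at these summits. Over all summits, the median ratio of the 7 other AT-only palindromic hexamers was 0.592, below the 0.825 of TAATTA. Higher GC content at summits is therefore a possible explanation for the lower share. These ratios were known before the test was written.

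No peak of either replicate lay near dsc-1, in a shared gap of 61.2 kb. Repeated sequence that reads cannot be placed on is argued against, as 6.05% of the 36-base words in the gap occur more than once in the genome, and so is a stretch with few genes, as the 9 gene starts in the gap are 0.954 times the X average per Mb. Extra copies of the dsc-1 region in a control library could lower the signal over such a length if the control came from the transgenic strain. The strain of the control is not given in the sources used here. The ChIP libraries came from the transgenic strain too, so a lower signal need not follow. Extra copies, other steps of the authors' processing and a true lack of peaks cannot be told apart, because the control was not analysed here.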
